A study of Mus musculus with 12 samples.

How the data were processed

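Liver RNA of male C57BL/6 mice, 6 weeks old, was measured before and after surgical removal of 2/3 of the liver (partial hepatectomy), per the labels. The 12 samples fall into 4 time points (0, 1.5, 12 and 24 h after surgery) with 3 mice each per the labels. The 3 arrays of a time point were taken as 1 per mouse and the mice of different time points as different animals, which the labels do not state. The array was a 1-colour (Cy3) Agilent platform that carries probes for messenger RNAs and for long noncoding RNAs. Per the file headers, Agilent Feature Extraction 10.5.1.1 read the spots, and the deposited files hold for every spot a processed intensity (background-subtracted and detrended within the array, linear scale), the median pixel intensity of the spot and of its local background, and quality marks. The deposited raw files also state the slide and the position of each array on it. The authors also deposited a table of log2 values for part of the probes. Their columns share nearly the same quantiles, and no label or header records how they were normalized, so they served only as an alternative.

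Each array held 39448 spots, of which 37831 were not controls and represented 37246 probes. Spots marked as outliers were dropped and the spots of 1 probe were averaged. The main values were log2 of the processed intensity minus the 75th percentile of the same array. Probes were kept where at least 3 of the 12 arrays had called them well above background, which left 31172 probes. Probes with an NM accession (22522, of which 19897 were kept) counted as protein-coding and all others (14724, of which 11275 were kept) as noncoding. Names came from a mouse gene reference table matched on accession: 21963 coding and 253 noncoding probes had a symbol, and the kept probes covered 17004 named genes. Noncoding transcripts without a symbol are given by the identifier in the files, so their identity rests on the array design. No coordinates are given.

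Differences were tested with limma 3.58.1 in R 4.3.3. A single linear model with 1 mean per time point was fitted to all 12 arrays, followed by empirical Bayes moderation. The contrasts were 1.5, 12 and 24 h against 0 h, and 24 h against 12 h, with an F test for a difference at any time point against 0 h. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the 31172 probes of a contrast, with a threshold of 0.05. Errors after ± are standard errors of the log2 fold change from that model. Errors and p-values measure the spread between arrays of the same time point, pooled over the 4 time points. The spread of the 24 h replicate 2 array therefore enters every contrast, also those without 24 h. Without that array 15268 probes passed at 12 h against 0 h, and 4774 with it. A group whose arrays were all called not well above background gives only a bound. In that case each of its signals was raised to at least the lowest normalized signal called well above background on the same array, and the fold against that floor is written as "at least". Such a bound holds for the main values, and other processing can give a smaller fold.

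27 gene lists (549 entries, 510 measured) were fixed from textbook knowledge of liver regeneration and of cells that a piece of liver can hold. They were tested with limma's camera on the brightest probe of each gene with a preset correlation between genes of 0.01, adjusted over the 81 tests of 27 lists in 3 contrasts against 0 h. Camera with an estimated correlation and fry were alternatives. Counts of list members past the threshold are given over all probes and, where they differ, adjusted over the list alone.

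Genes to name were chosen by a rule. For each contrast against 0 h it took, among probes past the threshold with a symbol or identifier whose groups did not overlap, the 6 coding genes with the highest and the 6 with the lowest log2 fold change, and the 4 noncoding transcripts at each end. It added up to 4 members of each list past the threshold, or the member with the smallest adjusted p where none passed. For 24 h against 12 h it took 4 at each end and up to 2 members per list, and well-known long noncoding RNAs were allowed in any contrast. Outside this rule, and chosen after their values were seen, are Hspa5 and Arntl at 12 h, Cyp1a2 at 24 h, and Mvk, Ppara, Cxcl10, Nr1i3 and Cyp3a41a for 24 h against 12 h. The model, lists, naming rule and the first set of alternatives were set before the data were examined.

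That set comprised normexp background correction with an offset of 50, quantile normalization, the authors' values, no filter on dim probes, a filter for probes well above background on all 12 arrays, 1 probe per gene, robust moderation with an intensity trend, a 2-fold minimum, the replicate number as a block, slide as a fixed block, only the groups compared, and leaving out each array in turn. Normexp was applied to the median spot intensity because the files hold no mean spot intensity. Added after the data were seen were a model of 11 arrays without the 24 h replicate 2 array, the same 11 arrays with quantile normalization, array weights, and slide as a random block.

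Slide and time point overlap. Slide 1 held the 3 arrays at 0 h and 1.5 h replicate 1, slide 2 held 1.5 h replicates 2 and 3 with 12 h replicates 1 and 2, slide 3 held 12 h replicate 3 with 24 h replicates 1 and 3, and slide 4 held 24 h replicate 2. With slide as a fixed block, 1.5 h against 0 h is therefore read within slide 1 and 24 h against 12 h within slide 3. No slide held 0 h together with 12 or 24 h, so the blocked contrasts of these times are sums of steps within slides. The step within slide 1 rests on 1 array at 1.5 h and that within slide 3 on 1 array at 12 h. The spread then comes from the other groups, and these lone arrays are assumed to vary like them. That model could be fitted for 30674 probes.

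The procedure was tested on simulated data with 200 changed probes among 30674 in each contrast. With the spread of all 12 arrays, 4-fold changes were recovered in 26% of cases at 1.5 h, 14% at 12 h, 40% at 24 h and 26% for 24 h against 12 h, and 2-fold changes in 0% of cases in each of these contrasts. With the spread of the arrays other than 24 h replicate 2, 4-fold changes were recovered in 80%, 88%, 86% and 80% and 2-fold changes in 21%, 16%, 23% and 15% of cases in the same order. No simulated change was called in the wrong direction. Of the unchanged probes 1, 0, 4 and 1 were called with the spread of all 12 arrays and 7, 5, 7 and 4 with the other, in the same order. The simulated noise was independent between arrays and had the same spread on each. It held no slide effect, no single deviating array and no shift of all probes, so these rates need not hold for the real data. With so few changed probes the adjustment is also stricter than at 12 h in the real data, where 4774 probes passed. Group sizes and spread were the same in each contrast and each was simulated 1 time. Differences between the rates of the contrasts are therefore no measure of power at a time point. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.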

Results

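RNA of regenerating mouse liver was profiled on 12 arrays, with 3 mice at each of 0, 1.5, 12 and 24 h after removal of 2/3 of the liver. The series asks which long noncoding RNAs change in the first day of regeneration, and the same array measured messenger RNAs. After the filter on dim probes, 19897 coding probes (88.3%) and 11275 noncoding probes (76.6%) remained. The signal at the 75th percentile lay between 443 and 599 on 11 arrays and was 6210 on the 24 h replicate 2 array. Between 62.8% and 85.4% of spots were called well above background, with the 4 highest values, 82.0% to 85.4%, on slide 2. No spot was saturated. The number of arrays, 3 per time point, limits the precision of every value.

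Across probes, which are not independent replicates, the log2 signals of the 3 arrays at 0 h correlated at r = 0.987, and those of 24 h replicates 1 and 3 at r = 0.986. The 1.5 h replicate 1 array correlated at 0.972 with the others of its time point and at 0.987 with a 0 h array of its own slide. The 24 h replicate 2 array, alone on its slide, correlated with the other 24 h arrays at 0.912 and 0.906. It took an extreme position on the first principal component, which held 53.4% of the variance. The second component, with 21.3%, separated the arrays at 0 and 1.5 h from those at 12 and 24 h. The 1.5 h replicate 1 array lay beside the 0 h arrays. The median log2 fold change of all probes was not 0: it was 0.16 at 1.5 h, 0.41 at 12 h and -0.15 at 24 h against 0 h, and -0.48 for 24 h against 12 h, with larger shifts among noncoding probes (0.36, 0.64, -0.33 and -0.99). Medians of gene lists are therefore given relative to it. The comparison includes noncoding probes, also in the camera tests. Coding probes alone had medians of 0.07, 0.24, -0.06 and -0.14 in the same order. Lists of coding genes thus lie lower against all probes than against coding probes at 1.5 and 12 h, and higher at 24 h. No list test against coding probes alone was run, so calls with small relative medians are open to this tilt.

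**Figure D1:**
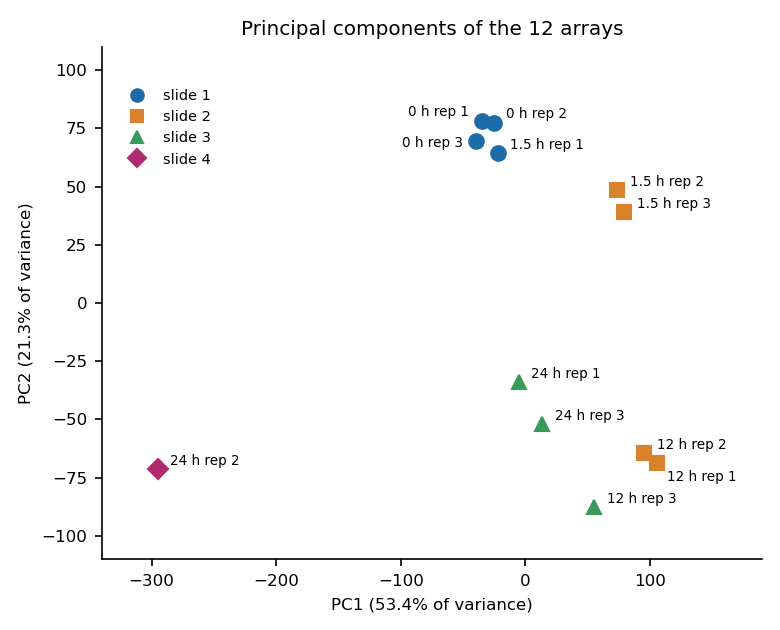
Each point is 1 of the 12 arrays, placed by its first 2 principal components of normalized log2 signal (no units), with color and shape for the slide. The 24 h replicate 2 array lies at -295.1 on the first component, and 1.5 h replicate 1 lies next to the 3 arrays at 0 h.

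The first comparison, 1.5 h against 0 h, asks which RNAs had changed soon after surgery. No sham-operated mice are among the 12 samples. At every time point, loss of liver mass therefore cannot be told apart from surgery and anaesthesia. 7 of 31172 probes passed the threshold, and all were higher at 1.5 h. Mt2, a metallothionein that binds zinc and copper, rose 30.8-fold (log2 4.95 ± 0.58, adjusted p = 0.0242). Nr4a1, an orphan nuclear receptor of the immediate early class, rose 24.0-fold (4.58 ± 0.59, adjusted p = 0.041), and Atf3, a stress-induced transcription factor, 15.4-fold (3.95 ± 0.41, adjusted p = 0.00918). S100a8 and S100a9, which together form the neutrophil protein calprotectin, rose 7.94-fold (2.99 ± 0.29, adjusted p = 0.00896) and 7.49-fold (2.91 ± 0.30, adjusted p = 0.00918). Cxcl2, a chemokine that attracts neutrophils, was at least 2.34-fold higher (adjusted p = 0.00896). The noncoding transcript AK085884, known by its cDNA identifier alone, rose 9.62-fold (3.27 ± 0.42, adjusted p = 0.041). For each of the 7, every array at 1.5 h lay above every array at 0 h. Such a separation, in either direction, was seen for 25.7% of all 31172 probes. It would be seen for 10% of unchanged probes if arrays differed by chance alone.

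The list of immediate early genes had an upward camera call at 1.5 h, which was lost with an estimated correlation. Of 35 measured members, 2 rose (Nr4a1 and Atf3) and 33 did not pass, while 17 rose when adjusted over the list alone. The list median was 1.21 above that of all probes on the log2 scale (camera adjusted p = 2.47e-18, and adjusted p = 0.0586 with an estimated correlation). Among neutrophil markers, S100a8 and S100a9 rose of 10 measured (5 adjusted over the list alone). For this list the relative median was 0.98, or 0.79 with dim members at their bounds (adjusted p = 5.02e-10, and 0.0254 with an estimated correlation). Mt2 was the member of the acute phase and cytokine list to rise among 36 (5 adjusted over the list alone). The list had a relative median of 0.13 (adjusted p = 0.000471, and adjusted p = 0.103 with an estimated correlation). No member passed in 4 further lists with a camera call: adipose markers (6 measured, relative median 0.86, or 0.32 with bounds, adjusted p = 0.0253), mitosis (29, 0.23, 0.0112), cholesterol synthesis (23, -0.31, 0.00613) and ribosome biogenesis (36, -0.24, 0.0345). Their adjusted p with an estimated correlation was 0.242, 0.467, 0.535 and 0.544. Within slides the cholesterol list turned upward (adjusted p = 0.254) and the ribosome list lost its call (adjusted p = 0.21). Leaving out single arrays ended some of these calls. The acute phase call ended without 1.5 h replicate 1 (adjusted p = 0.0859), the adipose call without 0 h replicate 2 or 1.5 h replicate 1 (0.0813, 0.0667) and the mitosis call without 0 h replicate 1 or 1.5 h replicate 1 (0.0971, 0.0667). The same held for cholesterol without 0 h replicate 2 or 1.5 h replicate 2 (0.076, 0.242) and ribosome biogenesis without 0 h replicate 2 or 3 or 1.5 h replicate 1 or 3 (0.0874, 0.17, 0.0522, 0.0998). The other 20 lists had no member past the threshold (1 higher each for clock genes and gluconeogenesis over the list alone) and adjusted p between 0.0621 and 0.998. Of these, macrophage markers (adjusted p = 2.65e-05) and gluconeogenesis (0.00763) gained an upward call within slides, where 1 array at 1.5 h stands against 3 at 0 h and is assumed to vary like the other groups. Without the 24 h replicate 2 array DNA replication gained a downward call (0.0185), and adipose markers and mitosis lost theirs (0.0735, 0.0522). Quantile normalization ended the calls of adipose markers, mitosis, cholesterol synthesis and ribosome biogenesis (0.113, 0.119, 0.0545, 0.305) and gave gluconeogenesis an upward call (0.0293).

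These 7 calls rest on few arrays: 3, 4 and 0 probes passed without 0 h replicate 1, 2 or 3, and 11 and 0 without 1.5 h replicate 2 or 3. 2 passed under normexp background correction, and 0 with the replicate number as a block or with the 2 groups fitted alone in limma. In the fit of all arrays 1999 probes had an unadjusted p under 0.05. Within slides, with that 1 array at 1.5 h, 15 probes passed (9 higher, 6 lower) and S100a9 was the 1 shared call (log2 3.15, adjusted p = 0.0436), all 7 keeping their direction. Without the 24 h replicate 2 array, which is in neither group, 177 passed (150 higher), these 7 among them.

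The second comparison, 12 h against 0 h, asks how the liver differed before hepatocytes replicate their DNA. 4774 probes passed, 2159 higher and 2615 lower. The protease inhibitor A2m was at least 987-fold higher (log2 11.15 ± 0.53 against unraised signals, adjusted p = 5.63e-06), the antibacterial lectin Reg3g at least 235-fold (adjusted p = 3.51e-06) and Tm4sf20, a membrane protein of the tetraspanin-like family, at least 105-fold (adjusted p = 3.79e-05). Lcn2, which binds bacterial siderophores, rose 439-fold (8.78 ± 0.58, adjusted p = 1.98e-05). The estrogen sulfotransferase Sult1e1 rose 182-fold (7.51 ± 0.75, adjusted p = 0.000238). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 6.92 ± 1.01 on the log2 scale, or 121-fold (adjusted p = 0.00154). Also lower were Keg1 (94.8-fold), the male-specific steroid dehydrogenase Hsd3b5 (75.8-fold), Tmem25 (54.5-fold), Mpp4 (at least 20.6-fold) and the elongation factor Ell3 (at least 19.7-fold), with adjusted p between 1.43e-05 and 0.0031. Over 12 alternative settings the log2 fold change ran from -5.83 to -1.15 for Mpp4 and from -6.43 to -1.08 for Ell3, and 11 kept each past the threshold.

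In the acute phase and cytokine list 28 of 36 members rose at 12 h and none fell (30 over the list alone). The relative median was 2.35 (adjusted p = 1.01e-18, and 0.0061 with an estimated correlation). Besides A2m and Lcn2, the endotoxin receptor Cd14 rose 128-fold (adjusted p = 0.000254) and Mt2 121-fold (6.92 ± 0.58, adjusted p = 0.000102). 7 of 10 neutrophil markers rose, among them S100a8 (30.4-fold, adjusted p = 1.43e-05), S100a9 (29.3-fold, adjusted p = 1.43e-05) and the granule gene Ngp (at least 20.1-fold, adjusted p = 0.000984). That list's relative median was 2.31, or 1.25 with bounds (adjusted p = 7.42e-07, and 0.0366 with an estimated correlation). 8 of 21 members of the endoplasmic reticulum stress list rose (14 rose and 1 fell adjusted over the list alone). Examples are the chaperone Hspa5 (4.72-fold, adjusted p = 0.00174) and Creld2 (7.98-fold, adjusted p = 0.000797). As a list they had a relative median of 0.52 (adjusted p = 0.00108, and adjusted p = 0.0586 with an estimated correlation). 7 of 36 ribosome biogenesis genes rose (10 over the list alone), for example Heatr1 (3.48-fold, adjusted p = 0.00231). The relative median of that list was 0.29 (adjusted p = 0.00388, and adjusted p = 0.454 with an estimated correlation). 4 of 6 adipose markers rose: the lipid droplet genes Cidec (67.3-fold, adjusted p = 0.00384) and Plin1 (at least 2.79-fold, 1 of 2 probes), the fatty acid carrier Fabp4 (7.71-fold) and Cfd (at least 2.94-fold). The relative median was 2.45, or 1.11 with bounds (adjusted p = 0.00175, and adjusted p = 0.103 with an estimated correlation).

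Fatty acid and cholesterol synthesis were among the lists with a downward call at 12 h. 12 of 16 fatty acid synthesis genes were lower and none higher. On the list level the relative median was -2.87 (adjusted p = 3.49e-12, and 0.0297 with an estimated correlation). The triglyceride hydrolase Pnpla3 fell 31.8-fold (-4.99 ± 0.36, adjusted p = 3.79e-05) and the lipogenic transcription factor Srebf1 15.5-fold (-3.96 ± 0.47, adjusted p = 0.000556). 17 of 23 cholesterol synthesis genes fell, among them Sc5d (12.7-fold, adjusted p = 0.000225). Their relative median was -2.36 (adjusted p = 4.47e-15, and adjusted p = 0.0717 with an estimated correlation) and shrank to -1.33 within slides. In the bile acid list 9 of 19 members fell and 2 rose (12 and 2 over the list alone), led after Cyp7a1 by the uptake transporter Slc10a1 (13.8-fold lower, adjusted p = 0.00148). Its relative median was -1.26 (adjusted p = 0.000124, and adjusted p = 0.183 with an estimated correlation). 13 of 31 xenobiotic metabolism genes fell (18 over the list alone), such as Fmo1 (5.83-fold, adjusted p = 0.000847), while 3 rose, led by Cyp2b10 (19.6-fold higher, adjusted p = 0.00686). The relative median was -1.32 (adjusted p = 9.86e-07, and adjusted p = 0.172 with an estimated correlation). Of 20 hepatocyte secreted proteins 4 fell, for example Igfals, the binding partner of circulating growth factors (11.3-fold, adjusted p = 0.00826), and Ttr (3.83-fold). They had a relative median of -0.49 (adjusted p = 0.0223, and adjusted p = 0.535 with an estimated correlation), a call that ended without 12 h replicate 2 or 3 (0.0516, 0.051). Their own median log2 fold change was -0.07, against 0.24 for all coding probes. Among 14 male-biased genes Hsd3b5 and Nudt7 (1 of 2 probes) fell. Their list had a relative median of -0.80 (adjusted p = 0.0472, and adjusted p = 0.454 with an estimated correlation), and this call ended without 0 h replicate 1 or 3 (0.0571, 0.0661) or 12 h replicate 2 or 3 (0.0858, 0.0663). Macrophage markers went both ways: Marco rose 5.38-fold (adjusted p = 0.00841) while Csf1r and Vsig4 fell 2.43-fold and 2.11-fold among 11 measured (3 fell over the list alone). That list's relative median was -1.09 (adjusted p = 0.0156, adjusted p = 0.561 with an estimated correlation, adjusted p = 0.757 within slides, and 0.0874 without 0 h replicate 2).

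The DNA replication and clock lists had a downward call as well. The hour of collection is not in the labels, and no unoperated mice were collected beside those at 12 h. For these and the other lists, a change at 12 h therefore cannot be told apart from a difference in time of day. 15 of 37 DNA replication genes fell and none rose (18 over the list alone). The relative median was -1.30 (adjusted p = 7.38e-08, and 0.0266 with an estimated correlation) and shrank to -0.55 within slides. Mcm10, needed to start replication forks, fell 16.3-fold (-4.03 ± 0.45, adjusted p = 0.000363). Thymidine kinase (Tk1) fell 10.6-fold (adjusted p = 0.0015) and the polymerase subunit Pole 6.04-fold (adjusted p = 0.00193). At 0 h the normalized log2 signals of Mcm10 were high, at 4.19 to 4.61, above those of Cyp7a1 (2.54 to 3.67). Whether a probe this bright reports replication was not tested, so the Mcm10 change alone is no measure of it. In the clock list 9 of 19 members fell and 4 rose (10 and 5 over the list alone). The relative median of the list was -1.62 (adjusted p = 3.17e-06, and 0.0297 with an estimated correlation). The fallen members included Usp2 (23.0-fold, adjusted p = 1.57e-05), Dbp (19.6-fold, adjusted p = 0.000175) and Wee1 (13.6-fold, adjusted p = 0.000452), and Arntl, which encodes the clock activator BMAL1, rose 7.22-fold (adjusted p = 0.00117).

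The remaining 13 lists had no camera call at 12 h. They were immediate early genes (8 of 35 rose, 10 over the list alone, and 2 fell, adjusted p = 0.169), G1 and S entry (2 of 18 rose, led by Cdkn1a at log2 2.70, and 1 fell, adjusted p = 0.669), mitosis (2 of 29 rose and 3 fell, 0.624), fatty acid oxidation and PPAR alpha targets (5 of 24 rose, 6 over the list alone, and 2 fell, 0.376) and gluconeogenesis (1 of 25 rose and 3 fell, 0.307). Female-biased genes (2 of 11 rose and 1 fell, 2 over the list alone, 0.994), lymphocyte markers (2 of 10 fell, and 1 rose over the list alone, 0.624), endothelial markers (1 of 13 rose and 3 fell, 0.0621), stellate cell markers (1 of 12 fell, 0.176) and bile duct markers (2 of 7 rose, 0.416) had none either, nor had erythroid (0 of 6, 0.97) and pancreas markers (0 of 10, 0.93). Among 11 well-known long noncoding RNAs, the small nucleolar RNA hosts Snhg1 (3.14-fold, adjusted p = 0.0174) and Snhg3 (3.40-fold, adjusted p = 0.0225) rose (list adjusted p = 0.235). Of 13 alternative settings, 8 kept Snhg1 past the threshold (log2 1.22 to 1.78 over all 13) and 6 kept Snhg3 (1.55 to 1.92). The median of all noncoding probes was 0.64. Immediate early genes gained an upward call within slides (0.00219) and endothelial markers a downward call without the 24 h replicate 2 array (0.0377), and the macrophage call ended under quantile normalization (0.101). The balance of members past the threshold also moved without the 24 h replicate 2 array. Mitosis then had 10 higher and 3 lower and gluconeogenesis 7 higher and 6 lower, with no list call (0.864 and 0.236).

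Of the noncoding transcripts, 714 were higher and 558 lower at 12 h, a balance that cannot be read apart from the shift of noncoding probes (median 0.64). AK008001 rose 84.4-fold (6.40 ± 0.67, adjusted p = 0.000285), and uc008mgp, uc009kuy and NR_003640 were at least 47.3-fold, 43.1-fold and 9.24-fold higher. AK018558 fell 178-fold (-7.48 ± 0.87, adjusted p = 0.000473) and AK019073 71.7-fold (-6.16 ± 0.79, adjusted p = 0.000815), while AK006955 and uc007uno were at least 32.2-fold and 9.27-fold lower. Of 11275 noncoding probes tested 11.3% passed, against 17.6% of coding probes, a difference that was not tested.

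Within slides, where no slide held both times, 1279 probes passed at 12 h (653 higher, 626 lower), 1030 of them shared, and 4642 of the 4657 calls that could be fitted kept their direction. Of the 100 calls of rule-named genes that could be fitted, 54 stayed past the threshold within slides and all kept their direction. Leaving out single arrays gave 2247, 2529 and 2514 calls for 0 h replicates 1, 2 and 3 and 2387, 3007 and 3125 for 12 h replicates 1, 2 and 3. Without the 24 h replicate 2 array 15268 passed (all 4774 included, 10035 higher and 5233 lower), and with the 2 groups fitted alone 15494 (10375 higher and 5119 lower), so the balance turned toward higher calls. Under normexp background correction 673 passed, of which 26.6% were higher against 45.2% of the 4774.

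The third comparison, 24 h against 0 h, asks what remained altered a day after surgery. 1698 probes passed, 882 higher and 816 lower. A2m was at least 257-fold higher (adjusted p = 2.88e-05), Reg3g at least 138-fold (adjusted p = 8.6e-06) and Igdcc4 at least 36.3-fold (adjusted p = 0.000206). Lcn2 rose 269-fold (8.07 ± 0.58, adjusted p = 8.12e-05) and Sult1e1 71.7-fold (6.17 ± 0.75, adjusted p = 0.00149). Chrna4, a nicotinic receptor subunit, was 74.8-fold lower (-6.22 ± 0.46, adjusted p = 9.01e-05), Hsd3b5 55.1-fold (-5.78 ± 0.55, adjusted p = 0.000395), the G protein regulator Rgs16 54.5-fold (-5.77 ± 0.47, adjusted p = 0.000176) and the lipogenic regulator Thrsp 52.5-fold (-5.71 ± 0.65, adjusted p = 0.00106). The uridine phosphorylase Upp2 fell 40.1-fold (-5.33 ± 0.73, adjusted p = 0.00305).

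In the acute phase and cytokine list 24 of 36 members rose at 24 h and none fell (28 over the list alone). Its relative median was 2.40 (adjusted p = 8.56e-26, and 0.00377 with an estimated correlation). Cxcl1, a chemokine for neutrophils, rose 42.6-fold (5.41 ± 0.51, adjusted p = 0.00037) and Mt2 40.6-fold (5.34 ± 0.58, adjusted p = 0.000865). 6 of 10 neutrophil markers rose, such as S100a8 (26.9-fold, adjusted p = 3.71e-05) and Retnlg (log2 4.25 ± 0.41, adjusted p = 0.000408). They had a relative median of 2.31, or 1.25 with bounds (adjusted p = 3.39e-08, and 0.0289 with an estimated correlation). 7 of 21 endoplasmic reticulum stress genes rose (11 over the list alone), for example Hspa5 (3.82-fold, adjusted p = 0.0101) and Sdf2l1 (7.52-fold, adjusted p = 0.0013). The list had a relative median of 1.25, or 1.19 with bounds (adjusted p = 4.29e-09, and 0.0105 with an estimated correlation). 9 of 24 fatty acid oxidation and PPAR alpha targets rose (14 rose and 1 fell over the list alone), led by the fatty acid hydroxylases Cyp4a14 (10.9-fold, adjusted p = 0.0309) and Cyp4a10 (8.65-fold, adjusted p = 0.0255). They had a relative median of 1.33 (adjusted p = 6.85e-09, and adjusted p = 0.0586 with an estimated correlation). Cidec, Fabp4 and Cfd rose among 6 adipose markers, at 34.1-fold, 11.1-fold and at least 9.97-fold. For these markers the relative median was 2.65, or 1.81 with bounds (adjusted p = 0.000471, and adjusted p = 0.0717 with an estimated correlation). No ribosome biogenesis gene of 36 passed although the list had a call with a relative median of 0.36 (adjusted p = 0.0289). That call was lost with an estimated correlation (adjusted p = 0.544) and without 0 h replicate 1 or 24 h replicate 2 (0.115, 0.963), and turned downward within slides (adjusted p = 0.308).

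7 lists had a downward camera call at 24 h. 11 of 16 fatty acid synthesis genes fell (14 over the list alone), Pnpla3 by 35.4-fold (-5.15 ± 0.36, adjusted p = 8.12e-05) and Srebf1 by 17.9-fold (-4.16 ± 0.47, adjusted p = 0.00106). The relative median was -2.43 (adjusted p = 2.17e-14, and 0.0266 with an estimated correlation). 13 of 31 xenobiotic metabolism genes fell and 1 rose (19 and 3 over the list alone), for example Cyp2c55 (25.3-fold lower, adjusted p = 0.00037) and Cyp1a2 (7.09-fold lower, adjusted p = 0.000297). Their relative median was -1.05 (adjusted p = 5.18e-08, and adjusted p = 0.124 with an estimated correlation). 4 of 14 male-biased genes fell (6 over the list alone), among them Susd4 (5.93-fold, adjusted p = 0.0118). They had a relative median of -0.77 (adjusted p = 0.000226, and adjusted p = 0.124 with an estimated correlation). In the bile acid list Slc10a1 (6.54-fold, adjusted p = 0.0191) and Slco1a1 (4.30-fold, adjusted p = 0.00256) fell with 2 others of 19 (8 fell and 1 rose over the list alone). Over 12 alternative settings the log2 fold change of Slc10a1 ran from -3.21 to -1.42, and 7 kept it past the threshold. The bile acid list had a relative median of -0.47 (adjusted p = 0.00272, and adjusted p = 0.333 with an estimated correlation). 9 of 19 clock genes fell and 3 rose (9 and 4 over the list alone), Dbp by 19.6-fold (adjusted p = 0.00037) and Usp2 by 12.3-fold (adjusted p = 0.000173), while Arntl rose 11.1-fold (adjusted p = 0.00106). Its relative median was -1.40 (adjusted p = 0.000595, and adjusted p = 0.0717 with an estimated correlation). Among hepatocyte secreted proteins Ttr fell (3.84-fold, 1 of 20, relative median -0.43, adjusted p = 0.0139, adjusted p = 0.517 with an estimated correlation, 0.254 within slides and 0.0871 without 24 h replicate 3). Lymphocyte markers had 0 of 10 past the threshold (1 lower over the list alone). Their relative median was -0.70, or -0.52 with bounds (adjusted p = 0.0316, adjusted p = 0.544 with an estimated correlation, 0.367 within slides, 0.0623 without 0 h replicate 2 and 0.112 without 24 h replicate 2).

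The other 14 lists had no camera call at 24 h. Cholesterol synthesis had 2 of 23 members lower (Sc5d and Insig1, 5 lower and 1 higher over the list alone, adjusted p = 0.162), DNA replication 3 of 37 lower (Tk1 at 6.17-fold, Mcm10 at 3.32-fold and Uhrf1 at 2.44-fold, the last by 1 of 4 probes and turned to 0.07 within slides, 0.0981) and mitosis 1 of 29 lower (Birc5, 0.611). G1 and S entry had 1 of 18 higher (E2f8, 0.135), immediate early genes 2 of 35 higher and 1 lower (3 and 1 over the list alone, 0.135), and gluconeogenesis 1 of 25 lower (0.0837). Female-biased genes had 1 of 11 higher (Cyp17a1, 11.5-fold) and 2 lower (Cyp2a4 and Cyp3a41a, 15.3-fold and 14.8-fold, 3 lower over the list alone, list adjusted p = 0.457). Macrophage markers had 1 of 11 higher (Marco, 7.39-fold, 0.184), endothelial markers 1 of 13 higher (Lyve1, 6.74-fold, 0.235), and stellate cell markers 1 of 12 higher (Dcn, 3 over the list alone, 0.611). Bile duct markers had 1 of 7 higher (Sox9, 4.17-fold, 0.0933) and pancreas markers 1 of 10 lower (Cela2a, 0.578), while erythroid markers (0 of 6, 0.561) and well-known long noncoding RNAs (0 of 11, 1 higher over the list alone, 0.624) had none. Several of these lists gained a call in other models. Without the 24 h replicate 2 array cholesterol synthesis (adjusted p = 0.0027, 7 lower and 1 higher), DNA replication (0.00258, 5 lower and 1 higher) and gluconeogenesis (0.027, 5 lower and 1 higher) were called downward. Quantile normalization called cholesterol synthesis (0.0169) and gluconeogenesis (0.0306) downward and ended the ribosome biogenesis call (0.174). Within slides macrophage markers (0.00214) and bile duct markers (0.011) were called upward. Noncoding transcripts gave 217 higher and 337 lower calls. Their balance cannot be read apart from the shift of noncoding probes (median -0.33). The median of all probes went from -0.152 to 0.125 without the 24 h replicate 2 array. uc009kuy was at least 26.2-fold and NR_003640 at least 4.66-fold higher, and uc009tel and AK044397 rose 21.4-fold and 19.9-fold. AK019073 was 76.4-fold, AK018558 29.8-fold, AK030382 25.9-fold and uc008txr at least 6.77-fold lower.

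The 24 h calls depended on slides and arrays more than those at 12 h: within slides, where slide 4 adds nothing, 73 probes passed (50 higher, 23 lower), 40 of them shared, and 1637 of 1652 fitted calls kept their direction. Of the 71 calls of rule-named genes that could be fitted, 10 stayed past the threshold within slides and 70 kept their direction. Without the 24 h replicate 2 array 5300 passed (3215 higher, 2085 lower), 1695 of the 1698 included, against 415, 512 and 776 without 0 h replicates 1, 2 and 3, 1082 with the replicate number as a block, 119 with the 2 groups fitted alone and 191 under normexp. Leaving out that array moved several of the folds at 24 h by more than 1.5 times, all still past the threshold. On the log2 scale Cidec went from 5.09 to 3.70, Igdcc4 from 7.29 to 6.55, Sult1e1 from 6.17 to 5.16, Cxcl1 from 5.41 to 4.81, Upp2 from -5.33 to -4.56, Tk1 from -2.63 to -2.02 and Cyp17a1 from 3.52 to 4.11. Of the noncoding transcripts uc009tel went from 4.42 to 2.93, uc009kuy from 5.61 to 4.70, AK044397 from 4.32 to 3.41 and AK018558 from -4.90 to -3.65. None of these 11 stayed past the threshold within slides (adjusted p from 0.0661 for AK044397 to 0.342 for uc009tel).

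**Figure D2:**
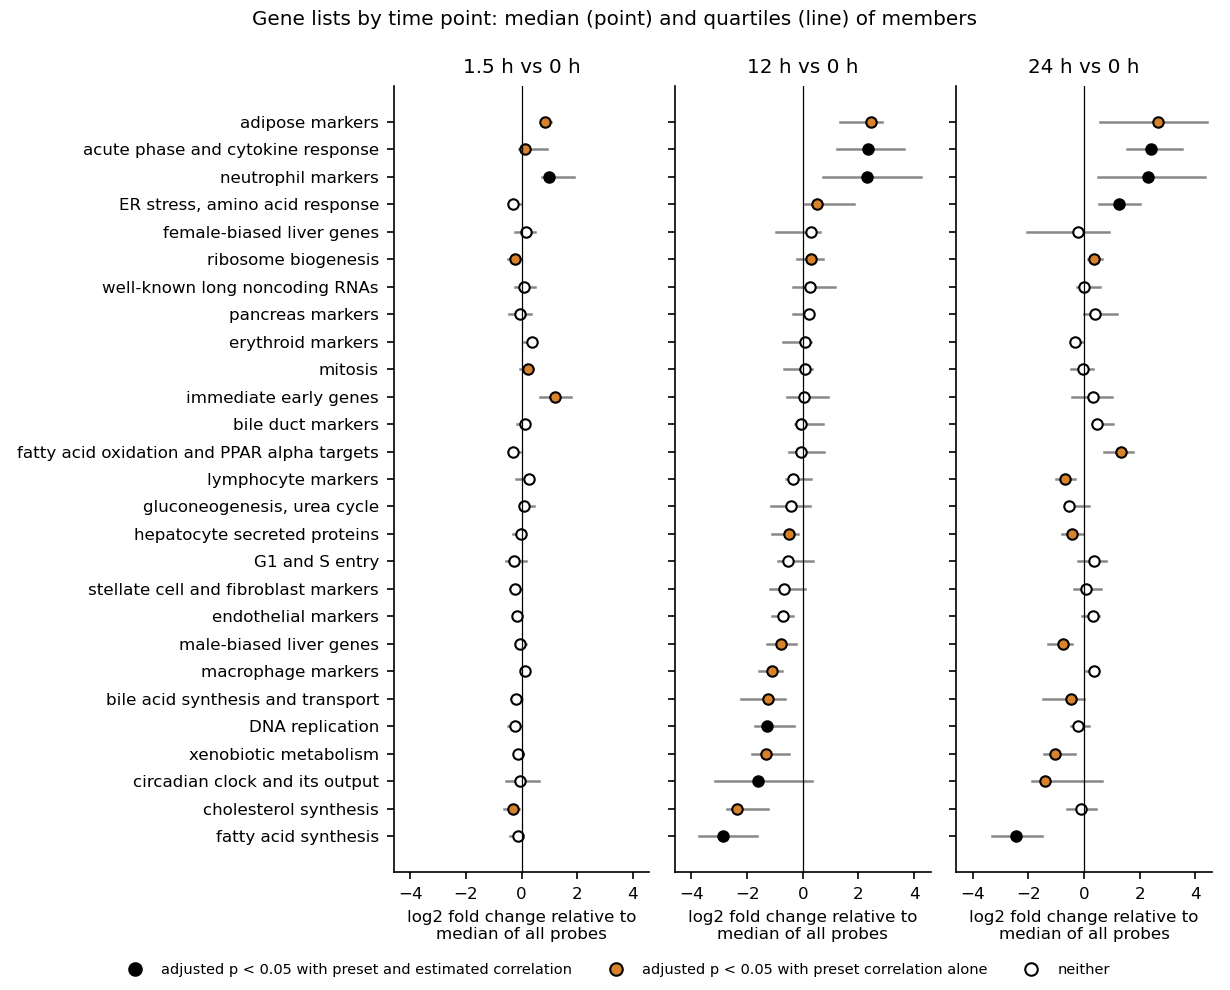
Each point is the median and each line the quartiles of the log2 fold changes against 0 h of the members of a list, relative to the median of all probes, and the fill marks the camera test. Acute phase and cytokine genes lay at 0.13, 2.35 and 2.40 and fatty acid synthesis genes at -2.87 and -2.43 at the 2 later times.

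The fourth comparison, 24 h against 12 h, asks what moved between the later times. 3984 probes passed, 1967 higher and 2017 lower at 24 h. Cholesterol synthesis genes rose: 12 of 23 passed (20 over the list alone) and none fell, among them Msmo1 (5.44-fold, adjusted p = 0.0289), Sc5d (4.00-fold, adjusted p = 0.0118) and Mvk (3.94-fold, adjusted p = 0.00394). 11 of the 12 had been lower at 12 h than at 0 h. Among all 1967 probes that rose, 1254 had been lower at 12 h. Both contrasts use the 12 h arrays, which favours such pairs. 11 of 37 DNA replication genes rose and 2 fell (14 and 2 over the list alone), with Mcm10 4.91-fold higher (2.30 ± 0.45, adjusted p = 0.0153). 10 of the 11 had been lower at 12 h. The limit given for the bright Mcm10 probe at 12 h holds here too. Fatty acid oxidation genes rose in 4 of 24 cases (10 rose and 4 fell over the list alone), for example Cyp4a14 (10.8-fold, adjusted p = 0.0256) and Ppara itself (4.01-fold, adjusted p = 0.0145, with 1 of its 3 probes at log2 0.42 and adjusted p = 0.316). The macrophage markers Adgre1 (4.28-fold, adjusted p = 0.013) and Vsig4 (2.74-fold, adjusted p = 0.0229) rose among 11.

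8 of 36 ribosome biogenesis genes fell between 12 and 24 h (10 over the list alone) and none rose, such as Heatr1 (2.63-fold, adjusted p = 0.0183). 6 of the 8 had been higher at 12 h. Among all 2017 probes that fell, 432 had been higher at 12 h, again with the 12 h arrays in both contrasts. In the acute phase and cytokine list 6 of 36 fell (9 over the list alone), among them Cd14 (6.18-fold, adjusted p = 0.041), and Cxcl10 rose 3.40-fold (adjusted p = 0.027). Of 31 xenobiotic metabolism genes 8 fell, led by Cyp2b10 (22.9-fold, adjusted p = 0.013), and 4 rose (5 over the list alone), led by the receptor gene Nr1i3 (4.73-fold, adjusted p = 0.00411). The female-biased genes Cyp2a4, Cyp2b9 and Cyp3a41a fell 9.20-fold, 8.84-fold and 4.40-fold. Outside the lists, Fam89a rose 42.6-fold (5.41 ± 0.55, adjusted p = 0.00163) and Tm4sf20, high at 12 h, fell 70.4-fold (-6.14 ± 0.62, adjusted p = 0.00163). Of the noncoding calls 371 were higher and 973 lower at 24 h, a balance that cannot be read apart from the shift of noncoding probes (median -0.99). AK008001 fell 17.7-fold (adjusted p = 0.00773) and uc009nzu rose 11.7-fold (adjusted p = 0.00413). Of the well-known long noncoding RNAs Tug1 rose 2.00-fold (adjusted p = 0.0384, its other probe at log2 -0.23 and adjusted p = 0.698) and Miat fell 2.30-fold (adjusted p = 0.0496), with 1 higher and 2 lower over the list alone.

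Within slide 3, which holds 12 h replicate 3 and 24 h replicates 1 and 3, 2730 probes passed (1650 higher), 1558 of them shared. That contrast sets 1 array at 12 h, assumed to vary like the other groups, against 2 at 24 h, and all 3 are part of the unblocked model too, so shared calls are no independent support. The count was 397 (333 higher, 64 lower) and 1232 (943 and 289) without 12 h replicates 1 and 2 and 10645 (3248 and 7397) without 24 h replicate 3, so the balance moved both ways with single arrays. It was 1226 (896 and 330) with the replicate number as a block, 2584 (1415 and 1169) without the filter on dim probes, 0 when the 2 groups were fitted alone, and 184 under normexp, of which 90.2% were higher against 49.4% of the 3984. Fam89a, when the 24 h replicate 2 array was left out, went from log2 5.41 to 6.01, Cyp2b10 from -4.52 to -3.79, AK008001 from -4.14 to -5.14, Cd14 from -2.63 to -3.61 and Msmo1 from 2.45 to 1.69, all still past the threshold.

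**Figure D3:**
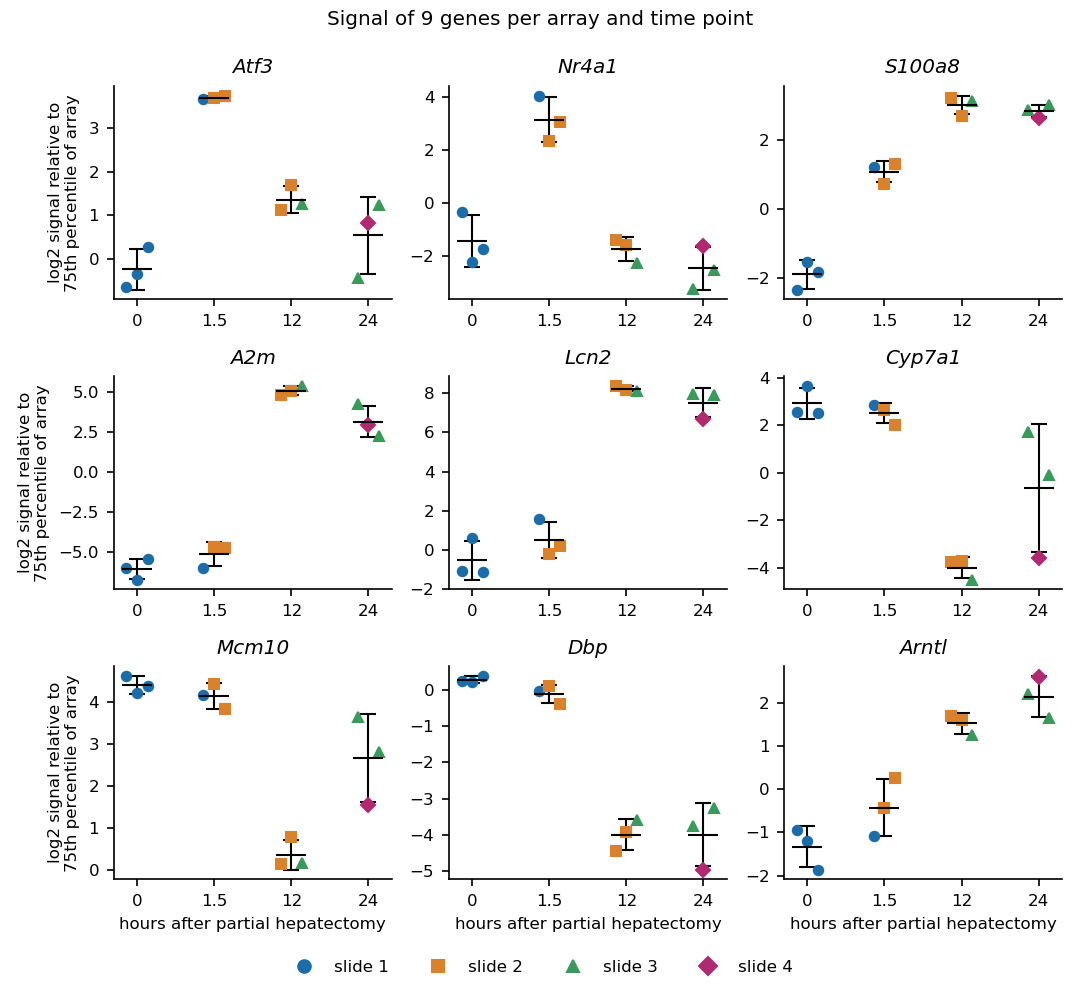
Each panel shows 1 gene, with 1 point per array (color and shape for the slide), log2 signal relative to the 75th percentile of its array on the vertical axis, hours after surgery on the horizontal axis, and the mean and SD of 3 arrays as bars. Lcn2 lay between -1.16 and 0.61 at 0 h and between 8.15 and 8.39 at 12 h.

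Calls at 12 and 24 h coincided for 1007 probes in the same direction (565 higher, 442 lower) and were opposite for 4. Independent lists would share 61.1 and 68.5 probes. The fold changes at 12 and 24 h had a covariance across probes of 0.402 against 0.13 in 100 simulations of unchanged groups against the same 0 h arrays, but their correlation, 0.434, lay below the 0.501 of these simulations. 6 of the 7 probes higher at 1.5 h were higher at 12 h (0.5 by independent lists, covariance 0.408) and 4 at 24 h (0.2, covariance 0.054, below the simulated value). The 3 arrays at 0 h are shared by these contrasts and cannot be split, so how much of the sharing comes from them is open. Of 2615 probes lower at 12 h than at 0 h, 1254 rose between 12 and 24 h and 13 fell, and of 2159 higher, 432 fell and 12 rose. Independent lists would give 165, 169.2, 139.7 and 136.2, but both contrasts use the 12 h arrays, which alone tilts them to opposite signs. 5065 probes differed at any time point by the F test. Without single arrays that count lay between 2355 (12 h replicate 1) and 13725 (24 h replicate 2), with 2674, 2811 and 2949 without 0 h replicates 1, 2 and 3, 3133 and 2995 without 1.5 h replicates 2 and 3 and 3124 without 12 h replicate 2.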

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

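No test in this part was chosen after its result was seen. 4 genes or transcripts passed the threshold in opposite directions at 12 and 24 h against 0 h. Since they were picked for this against shared 0 h arrays, a difference between the 2 times follows from the selection, and its p-value is left out. With slide as a fixed block none of the 8 calls against 0 h stayed past the threshold. Gm4952, a predicted gene, was lower at 12 h (log2 -2.52, adjusted p = 0.00435) and higher at 24 h (2.07, adjusted p = 0.0257), a difference of 4.595 ± 0.45. Within slides it stood at -2.50 (adjusted p = 0.138) and 2.64 (adjusted p = 0.397). Olfr1033, which encodes an odorant receptor, stood at -1.80 (adjusted p = 0.0337) and 2.37 (adjusted p = 0.0218), a difference of 4.18 ± 0.50, and within slides at -1.80 (adjusted p = 0.276) and 1.93 (adjusted p = 0.562). Plscr2, a phospholipid scramblase, stood at -1.15 (adjusted p = 0.036) and 1.34 (adjusted p = 0.0377), a difference of 2.49 ± 0.32, and within slides at -1.11 (adjusted p = 0.0952) and 0.91 (adjusted p = 0.447). The noncoding transcript uc007hkd stood at -1.06 (adjusted p = 0.0282) and 1.19 (adjusted p = 0.0339), a difference of 2.25 ± 0.28, and within slides at -1.55 (adjusted p = 0.0741) and 0.68 (adjusted p = 0.696). Plscr2 and uc007hkd are outside the naming rule and were named because they met this criterion.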

How the results depend on the processing

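Alternatives chosen after the data were seen were the 11 arrays without 24 h replicate 2, these with quantile normalization, array weights and slide as a random block. The cause of a shift was not tested unless named. Counts at 1.5, 12 and 24 h against 0 h, 24 h against 12 h and at any time point were 7, 4774, 1698, 3984 and 5065. Normexp gave 2, 673, 191, 184 and 683, with 118 shared calls at 12 and 24 h (1007), 1 at 1.5 and 12 h (6), 1 at 1.5 and 24 h (4) and 103 of the 238 calls of named genes. Its shares of higher calls were 26.6% at 12 h and 90.2% for 24 h against 12 h (45.2% and 49.4%). The authors' values gave 20 at 1.5 h, with 80% higher (100%) and 13 and 9 shared with 12 and 24 h. The filter on all 12 arrays gave 18 at 1.5 h, no filter 2584 for 24 h against 12 h, robust moderation 15 at 1.5 h and quantile normalization 7807 at any time point. Slide as a fixed block gave 15, 1279 and 73 against 0 h and 94 of 229 named calls. Slide as a random block (consensus correlation 0.853) gave 65, 2647 and 288. Only the groups compared gave 0, 15494, 119 and 0 in the 4 contrasts. The 11 arrays gave 177, 15268, 5300 and 13725 (1.5, 12 and 24 h, any). With quantile normalization they gave 141, 12001, 5009 and 12371, with 5 calls of cell type markers (8 of 27). Array weights (0.043 for 24 h replicate 2) gave 11864, 18133, 8745, 10494 and 23048.

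With an estimated correlation 10 of the 34 list calls held, and 3 of the 8 for cell type markers. Fry held 25. Of the 47 list tests without a call, 8 gained one under normexp, 3 under quantile normalization, 5 within slides and 5 in the model of 11 arrays. Leaving out each array of the groups compared gave 0 to 11 calls at 1.5 h, 2247 to 3125 at 12 h, 415 to 5300 at 24 h, 397 to 10645 for 24 h against 12 h and 2355 to 13725 at any time point, and turned no call of a named gene or list. Of the named calls it held 134 to 138 of 184 without a 0 h array, 0 to 7 of 7 without a 1.5 h array, 93 to 123 of 156 without a 12 h array and 108 to 123 of 129 without a 24 h array.

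Directions turned in few cases. Under normexp, Ms4a1 at 12 h went to 0.17, Fosl1 at 24 h to -0.41, and uc007vfy and E2f2 for 24 h against 12 h to -0.03 and -0.31. The lists of hepatocyte secreted proteins (adjusted p = 8.74e-05), male-biased genes (0.0203) and xenobiotic metabolism (0.000258), without a call at 1.5 h, turned upward there. Within slides Uhrf1 at 24 h went to 0.065, cholesterol synthesis at 1.5 h turned upward (adjusted p = 0.254) and ribosome biogenesis at 24 h downward (adjusted p = 0.308). Quantile normalization and the authors' values turned no called gene or list, with 226 of 238 and 170 of 173 named calls held.

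The labels do not say what the replicate number marks. Deviations from the group means correlated at -0.423 to 0.413 (median -0.0419) over 18 pairs of arrays with the same number. Over 36 pairs with different numbers they correlated at -0.492 to 0.507 (median 0.0345). Pairs with the same number were thus no more alike. The range is set by deviating arrays such as 1.5 h replicate 1 and 24 h replicate 2 (0.507), so this cannot exclude shared mice or days. The replicate block gave 0 at 1.5 h, 1082 at 24 h, 1226 for 24 h against 12 h and 3023 at any time point, kept 181 of 229 named calls and changed no list call. Signal over background limits the dim probes, since 62.8% to 85.4% of spots per array were called well above it.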

Other observations

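The tests of a signal-dependent distortion and of another time point with the brightness trend removed and the values without the 24 h replicate 2 array were chosen after the results were seen, the other tests before, and the genes of this paragraph were chosen after their values were seen. Classic immediate early genes outside the 7 calls at 1.5 h had Fos 9.16-fold (log2 3.20 ± 0.66, adjusted p = 0.243), Maff 6.04-fold (adjusted p = 0.309), Klf4 5.42-fold (adjusted p = 0.139), Jun 3.74-fold (adjusted p = 0.632) and Myc 2.66-fold (adjusted p = 0.517) above 0 h, none past the threshold. Without the 24 h replicate 2 array Fos, Maff, Klf4 and Jun passed (adjusted p = 0.0235, 0.0179, 0.0179 and 0.0291) and Myc did not (0.0722). Socs3, the feedback inhibitor of cytokine receptors, rose 13.9-fold at 12 h (adjusted p = 0.00206) and 13.5-fold at 24 h (adjusted p = 0.00598), and the serum amyloid genes Saa1 and Saa2 rose 7.51-fold and 15.3-fold at 12 h (adjusted p = 0.00389 and 0.00255). Slc13a5, a citrate importer of hepatocytes, rose by log2 5.63 ± 0.30 at 12 h (adjusted p = 1.23e-05) and 2.83 ± 0.30 at 24 h (adjusted p = 0.00078). Hlf, a clock-controlled transcription factor, fell 4.47-fold at 12 h (adjusted p = 0.00628) and rose 5.18-fold from 12 to 24 h (adjusted p = 0.0103). Within slides Socs3 at 12 and 24 h (log2 3.87 and 3.48, adjusted p = 0.102 and 0.412), Slc13a5 at 24 h (2.90, adjusted p = 0.146) and Hlf at 12 h (-1.85, adjusted p = 0.124) were no longer past the threshold, and Jun at 1.5 h was (adjusted p = 0.0484). Not past the threshold at 24 h were Pcna at log2 0.28 ± 0.25 (adjusted p = 0.551), Mki67 at -0.85 ± 0.45 (adjusted p = 0.315) and Ccnd1 at -0.97 ± 0.67 (adjusted p = 0.44), and albumin (Alb) at -0.96 ± 0.47 (adjusted p = 0.278).

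Calls among noncoding probes were counted by the source of their identifiers, and no test compared the sources. Transcribed ultraconserved elements gave 30 higher and 0 lower calls of 572 at 12 h against 0 h, and 1 higher and 78 lower for 24 h against 12 h. Full-length cDNA transcripts (AK identifiers) gave 346 higher and 265 lower of 5948 at 12 h, and 159 higher and 556 lower for 24 h against 12 h. The medians of these dim classes shifted in the same directions (at 12 h 0.91 and 0.63, against 0.24 for coding probes, and for 24 h against 12 h -1.39 and -1.01, against -0.14), so the balance of higher and lower calls cannot be read apart from the shift.

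The 24 h replicate 2 array stood apart from the other 24 h arrays. RNA of another time point is argued against: over 13502 probes its change from 0 h correlated at 0.303 with the other 24 h arrays, 0.121 with 12 h and -0.215 with 1.5 h, a lead of 0.181 for its own label. With the brightness trend removed the lead was 0.141, and the correlation was 0.332 to 0.348 with single 24 h arrays and 0.167 to 0.223 with single 12 h arrays. Its signals as a whole lay closest to a 0 h array (r = 0.917), yet its Lcn2 signal, at 6.68, was far from 0 h (0.61 at most) and nearer to the other 24 h arrays (7.93 and 7.98) and those at 12 h (8.15 to 8.39). Its Cyp7a1 signal, at -3.60, was like those at 12 h (-4.51 to -3.71) and unlike the other 24 h arrays (1.71 and -0.09). A distortion that grows toward dim probes is consistent with the values: the dimmest quintile of probes deviated by -1.58 and the brightest by 0.11, a difference of 1.69 against 0.063 to 0.805 on the other arrays. Its source, such as the scanner setting, the labelling or the slide it sits on alone, stays open, and no biological explanation was tested.

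The clock list had a call at 24 h (adjusted p = 0.000595), which was lost with an estimated correlation (adjusted p = 0.0717). That time is a full day after surgery, when an unshifted rhythm would return to its level at 0 h if mice were collected at the same hour. A slide effect is argued against: over 11 called members the log2 fold change within slides was 0.955 of the unblocked one in the median (0.752 to 1.287, lower quartile 0.873), although of these calls Dbp alone stayed past the threshold (adjusted p = 0.0333). The 24 h replicate 2 array alone is argued against as well, since the ratio without it was 0.987 (0.806 to 1.258). The hour of collection is not in the labels, so a difference in hour and a shift of the clock by surgery, feeding or anaesthesia stay open and untested.

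The list of male-biased liver genes had a downward call at 12 h (adjusted p = 0.0472), with 2 of 14 members past the threshold, led by Hsd3b5. It was lost with an estimated correlation (adjusted p = 0.454) and in 4 of the models that left out an array (adjusted p = 0.0571 to 0.0858). A lower share of hepatocytes cannot be told apart from a change in these genes: hepatocyte secreted proteins lay 0.31 above the male-biased genes in the median log2 fold change, within the bound that a lower share allows, but of 5 lists of other liver cells only 2 had a median above that of the hepatocyte list. A slide effect is argued against: within slides the list median relative to all probes was -0.71, against -0.80 unblocked (adjusted p = 0.00108), and the ratio for Hsd3b5, the 1 called member that could be fitted, was 1.09. As for the clock list, this rests on lone arrays within slides that are assumed to vary like the other groups. A change in growth hormone signalling, which sets the sex bias of these genes, stays open as a hypothesis and was not tested.

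Other splits of the arrays bear on the counts. The splits of 3 against 3 arrays are 10 for each contrast, too few for a share under 0.05: the real split gave 7, 4774, 1698 and 3984 probes at 1.5, 12 and 24 h against 0 h and 24 h against 12 h, and the highest other split 0 in each. For the F test 1 of 100 drawn splits of the 12 arrays into 4 groups, the real one with 5065, gave as many. The highest other gave 516 and 93 gave 0. The draws moved arrays freely between slides, while the real groups partly follow the slides (consensus correlation within slides 0.853). That estimate includes the deviating 24 h replicate 2 array, alone on its slide, and how far this array sets it was not tested. Deviations from the group means correlated at -0.115 to 0.217 (median 0.046) between arrays of different times on 1 slide. Such deviations no longer hold a slide difference that a whole group shares. A free regrouping of the arrays thus rarely gave so many, but the draws cannot tell a difference between times from one between slides.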
